A study of Drosophila melanogaster with 13 samples.

How the data were processed

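RNA was measured in cultured ovarian somatic cells of Drosophila, a line derived from the somatic follicle cells of the ovary. The cells were transfected with small interfering RNA (siRNA) against Yb (group siYB, gene fs(1)Yb), against Armitage (group siARMI, gene armi) or against luciferase, a gene the cells lack (group siLUC, the control). Each group had 3 libraries, which per the labels' protocols were poly(A)-selected and made with a directional kit after transfection at 0 and 48 h and harvest at 96 h. Their titles carry the tag RZ, which no label explains. Another 4 libraries, 2 from a pulldown of RNA labelled for 10 min with 4 mM 4-thiouridine and 2 of its input, were not analysed here.

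The authors deposited 2 tables of results, 1 for siYB against siLUC and 1 for siARMI against siLUC. Per the file headers, each row of the authors' deposited tables gives a mean normalised read count over the libraries compared, a log2 fold change, the error of that log2 fold change, a p-value and an adjusted p-value. The submitters' processing notes name Bowtie, STAR, HOMER, Salmon 1.7.0, edgeR and DESeq2, with no roles. The column names are those of a DESeq2 result per the file headers. The log2 fold changes in the authors' deposited tables had been shrunk toward 0, as their ratio to the error does not give the listed p-value. In the siYB table the shrinkage left 8458 of 8480 rows (99.7%) with an error under 0.01 and a log2 fold change of about 0. For those rows the p-value carries information and the size of the change does not, and the sign is uncertain. The genome build and annotation of the authors' counting are not given in the sources used here. Positions of genes come from the annotation of BDGP6.54 (Ensembl release 115).

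The siYB table had 8297 gene rows and 183 transposon rows, and that of siARMI had 8291 and 184. Of these, 2 rows in each had no p-value. Row names ending in a strand tag were read here as the antisense strand of a transposon, which the files do not document. Of 8401 gene names in either table, 8199 matched a symbol in the reference names. The sign of each comparison was taken as knockdown against control, since the targeted gene was negative in its own table.

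The tables hold no per-library values. The planned count tests were therefore not run, and the authors' own adjusted p-values (Benjamini-Hochberg, recomputed here to a largest difference of 3.63e-14) with a threshold of 0.05 define a called row. Depth per library is not given, and with it the precision that depth gives is unknown. The mean normalised counts summed to 1642730 in the siYB table and 6210720 in the siARMI table, on scales set by each table's own normalisation. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

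Gene lists were fixed before the data were examined, and 29 of them had at least 5 measured members. They covered the piRNA pathway, transposons, stress and immune responses, signalling pathways, markers of follicle cells and of other cell types, and housekeeping complexes. Of the symbols asked for, 667 of 795 matched a row of the siYB table and 671 of 793 of the siARMI table, 18 in each through a synonym. Lists defined by a name pattern, such as oxidative phosphorylation subunits (71 and 69 rows), count only the rows they matched. They match in full by construction and raise these totals. Lists were tested with limma 3.58.1 (R 4.3.3), function cameraPR, on the signed normal quantile of the p-value, with a preset correlation of 0.01 between members and Benjamini-Hochberg adjustment over the lists. An estimated correlation needs per-library values and was not obtained. Shares of called rows were compared with Fisher's exact test, two-sided, in scipy 1.17.1. Rows of a table are not independent replicates, so those p-values describe the rows of these tables.

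The comparison of the knockdowns used 8367 rows with a p-value in both tables. Chance agreement from shared controls was simulated with 20 draws of unchanged groups against the same 3 control libraries, once with equal spread and once with the siYB spread widened 5.00 times. The 5.00 is a ratio of fold-change errors between the tables, applied here to the spread of the siYB libraries. Since control spread enters the error too, that setting widens the siYB error by less than the observed ratio. The share of same signs was simulated again, also with 20 draws, for rows called after Armitage knockdown, with the siARMI effects as deposited and no siYB effect. That both tables use the same siLUC libraries is taken from the series design. The difference between the knockdowns was the siARMI minus the siYB log2 fold change, with the error from both deposited errors, a two-sided normal p and Benjamini-Hochberg adjustment. It was limited to the 22 rows whose siYB estimate had not been shrunk to 0, a limit chosen after seeing the data. A siYB log2 fold change was also rebuilt from the mean normalised counts of both tables and the siARMI fold change, after scaling by the median ratio of 3.69. For the 22 rows it had the sign of the deposited value in 22 and differed from it by a median of 0.13 and by 0.87 at most. Among rows shrunk to 0 the rebuilt sign was opposite in some, such as armi (rebuilt 0.29, deposited −1.15e-05) and stg (rebuilt −0.40, deposited 4.58e-06). It was the same in others, such as NetA (rebuilt −1.56, deposited −7.26e-06). The siYB list tests, same-sign shares and correlations use the deposited signs.

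Genes were named by a rule fixed before the data were examined. It takes fs(1)Yb, armi and ex. In each comparison it takes the 10 called rows with the largest rise and the 10 with the largest fall whose mean count was at or above the table's median. It takes up to 4 members of each list with the smallest p, and every measured member of the piRNA biogenesis, nuclear silencing and transposon lists. It also takes the 5 largest differences between the knockdowns per direction. Antisense transposon rows, and the sense rows of NOF and HMS-Beagle2, were named after their values were seen.

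The scripts (Python 3.11.15, numpy 2.4.6, pandas 2.3.3) were tested on simulated statistics. For 8478 simulated siYB rows, 75% of rows moved by 4 standard errors and 98% of rows moved by 6 were recovered, with 3.89% false calls. For 8473 simulated siARMI rows the shares were 78% and 100%, with 5.32% false calls. Unmoved simulated rows had the spread that chance gives, which the authors' p-values do not have in the siYB table. The shares check the scripts and do not give the sensitivity of the siYB calls. Alternatives covered the threshold, a minimum fold, the adjustment, an expression filter, median-centring, the statistic and correlation of the list test, transposon strand, and the covariance from shared controls.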

Results

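Yb and Armitage are factors of the somatic piRNA pathway, in which small RNAs bound to Piwi silence transposons in the follicle cells of the fly ovary. Transcript levels were compared between ovarian somatic cells depleted of either factor and control cells treated with siRNA against luciferase, with 3 libraries per group. All fold changes are those of the authors' deposited tables, given as log2 fold change ± the deposited error, and were shrunk toward 0 by the authors.

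The siRNA against Yb lowered fs(1)Yb (FBgn0000928; chromosome X, 2720468 to 2724158, plus strand, BDGP6.54), with a log2 fold change of −2.17 ± 0.51 in the authors' deposited table (adjusted p = 6.04e-04, Benjamini-Hochberg). The siRNA against Armitage lowered armi (FBgn0041164; chromosome 3L, 3461317 to 3466314, plus strand, BDGP6.54), with a log2 fold change of −1.92 ± 0.07 in the authors' deposited table (adjusted p = 3.98e-174, Benjamini-Hochberg). The transcript of armi did not pass the test after Yb knockdown (unadjusted p = 0.820 in the authors' deposited table). After Armitage knockdown fs(1)Yb was lower, at −0.26 ± 0.07 (adjusted p = 9.03e-04, Benjamini-Hochberg, in the authors' deposited table).

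Armitage knockdown raised long terminal repeat (LTR) retrotransposons of the gypsy group, the families known to be active in follicle cells. In the authors' deposited table mdg1 was higher by 7.52 ± 0.09 and 412 by 6.03 ± 0.09, 297 by 5.94 ± 0.10, Tabor by 5.20 ± 0.20 and Stalker2 by 4.97 ± 0.07. Rises of 4.84 ± 0.31 for gypsy5, 4.83 ± 0.08 for blood, 4.36 ± 0.21 for Stalker, 4.08 ± 0.07 for gypsy and 3.84 ± 0.10 for Quasimodo followed in the authors' deposited table. Of 23 measured members of the gypsy-group list 17 rose, 1 fell and 5 did not pass the test, and the counts adjusted over the list alone were 17 and 1. The member that fell was gypsy3_new, at −1.90 ± 0.33 in the authors' deposited table. Among the members that did not pass, springer stood at 0.08 ± 0.05 and mdg3 at 0.11 ± 0.08 in the authors' deposited table. The list as a whole was higher than other rows (adjusted p = 4.32e-75, cameraPR).

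Part of the other transposons rose after Armitage knockdown. Of 45 measured members of that list 18 rose and 3 fell, or 21 and 3 adjusted over the list alone, and the list was higher than other rows (adjusted p = 0.00607, cameraPR). Its adjusted p was 0.144 with a preset correlation of 0.05. Among its members the I-element, a non-LTR element, was higher by 2.59 ± 0.34, GATE by 2.45 ± 0.21, flea by 1.87 ± 0.12, Juan by 1.02 ± 0.11 and copia by 0.28 ± 0.08 in the authors' deposited table. Also outside the gypsy-group list, NOF was higher by 4.11 ± 0.22 and HMS-Beagle2 by 2.25 ± 0.16 in the authors' deposited table. Of the telomeric elements HeT-A was higher by 0.35 ± 0.14 and TART-A by 0.45 ± 0.21 in the authors' deposited table, while TAHRE stood at −0.06 ± 0.25 and did not pass the test.

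Among transposon rows called after Armitage knockdown, sense rows were mostly higher and antisense rows mostly lower. Among 91 sense rows 41 were called higher and 5 lower in the authors' deposited table, and among 93 antisense rows 8 were called higher, 24 lower and 61 did not pass. The median log2 fold change over all antisense rows was −0.09 in the authors' deposited table, and 47 of 84 families measured on both strands had opposite signs. The called sense and antisense rows differed in direction (p = 7.95e-09, Fisher's exact test, two-sided). Antisense rover was lower, at −2.29 ± 0.10, as were antisense gypsy5 at −1.81 ± 0.09, antisense gtwin at −1.57 ± 0.07, antisense 412 at −1.50 ± 0.07 and antisense mdg1 at −1.33 ± 0.09 in the authors' deposited table. Antisense roo and antisense Quasimodo rose instead, by 2.18 ± 0.09 and 0.93 ± 0.14 in the authors' deposited table. Sense transposon rows were called higher more often than genes, 45.1% of 91 against 14.9% of 8289 (p = 1.06e-11, Fisher's exact test, two-sided).

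**Figure D1:**
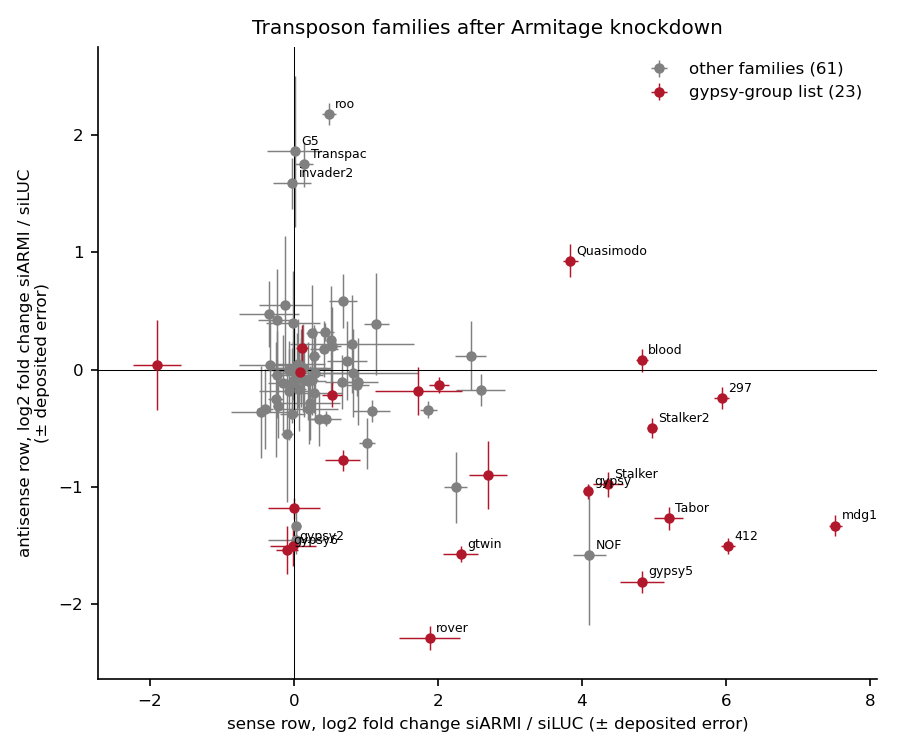
Each point is a transposon family after Armitage knockdown, with the log2 fold change (siARMI over siLUC) of its sense row on the x axis and of its antisense row on the y axis, and bars for the error in the authors' deposited table. The 23 families of the gypsy-group list (red) include mdg1 at 7.52 in sense and −1.33 in antisense, and 61 families outside that list (grey) lie mostly near 0. The list was a chosen one and does not hold every element of that group, gypsy12 for example.

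Genes, here all rows other than transposon rows, also changed after Armitage knockdown. Of 8289 genes tested 2348 (28.3%) passed the test, 1239 of them higher and 1109 lower in the authors' deposited table. Cda5, a chitin deacetylase, rose by 6.01 ± 0.18 and stan (starry night), an atypical cadherin of planar polarity, by 4.35 ± 0.19 in the authors' deposited table. They and 8 gypsy-group transposons made up the 10 largest rises among rows at or above the median count. The gene ex (expanded; FBgn0004583; chromosome 2L, 431227 to 448701, plus strand, BDGP6.54), a regulator of the Hippo pathway, was higher by 2.45 ± 0.12 in the authors' deposited table (adjusted p = 2.78e-91, Benjamini-Hochberg). Among rows at or above the median count the largest fall was that of NetA, which encodes the guidance cue Netrin-A, at −4.57 ± 0.16 in the authors' deposited table. Zasp66, a Z-disc protein gene, fell by 4.00 ± 0.21 in the authors' deposited table, and nab, a transcriptional cofactor gene, stood at −3.52 ± 0.20 in the authors' deposited table. CG9336 was lower at −2.99 ± 0.14, CG34398 at −2.96 ± 0.13, CG9747 at −2.64 ± 0.16, olf413 at −2.51 ± 0.16, Nepl4 at −2.43 ± 0.15 and MFS3 at −2.27 ± 0.11 in the authors' deposited table. With an absolute log2 fold change of at least 1 asked for as well, 559 rows of genes and transposons together passed, against 2426 without it.

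Heat shock genes rose together after Armitage knockdown. Of 17 measured members 12 rose and 0 fell, and adjusted over the list alone the counts were 12 and 0, with 0 lower at an unadjusted p under 0.05 (list adjusted p = 2.27e-13, cameraPR). In the authors' deposited table the chaperone genes Hsp68, Hsp67Ba, Hsp23 and Hsp26 were higher by 1.84 ± 0.09, 1.68 ± 0.09, 1.59 ± 0.08 and 1.37 ± 0.08. Counts of the near-identical Hsp70 copies are uncertain, and without them 9 of 12 members rose in the authors' deposited table. The list of JNK pathway genes and Jun/Fos targets was also higher (adjusted p = 0.00131, cameraPR), with 5 members up, 1 down and 5 not past the test, and 5 and 1 adjusted over the list alone. The matrix metalloproteinase genes Mmp2 and Mmp1 rose by 2.17 ± 0.13 and 1.65 ± 0.08, the JNK phosphatase puc by 0.56 ± 0.11 and Jra, which encodes Jun, by 0.54 ± 0.11 in the authors' deposited table. By ranks the adjusted p of that list was 0.0755 (cameraPR).

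Part of the genes of proliferation and of mitochondria were lower after Armitage knockdown. In the cell cycle and replication list 13 of 27 members fell, 0 rose and 14 did not pass, with 13 and 0 adjusted over the list alone and 0 higher at an unadjusted p under 0.05 (list adjusted p = 4.62e-04, cameraPR). The phosphatase gene stg, which drives entry into mitosis, was lower at −1.17 ± 0.10, and the replicative helicase genes Mcm3, Mcm2 and Mcm5 at −0.70 ± 0.09, −0.68 ± 0.07 and −0.58 ± 0.08 in the authors' deposited table. Among 69 subunits of oxidative phosphorylation 31 fell, 1 rose and 37 did not pass, with 36 lower and 1 higher adjusted over the list alone (list adjusted p = 8.76e-04, cameraPR). UQCR-C1 and UQCR-C2 of respiratory complex III were lower at −0.51 ± 0.07 and −0.35 ± 0.07, and ND-24 and ND-19 of complex I at −0.49 ± 0.10 and −0.51 ± 0.11 in the authors' deposited table. Of 72 mitochondrial ribosomal protein genes 20 fell, 0 rose and 52 did not pass, with 19 and 0 adjusted over the list alone and 0 higher at an unadjusted p under 0.05 (list adjusted p = 0.00607, cameraPR), for example mRpS30 at −0.41 ± 0.09 and mRpL19 at −0.54 ± 0.15 in the authors' deposited table. With a preset correlation of 0.05 the adjusted p of both mitochondrial lists was above the threshold, at 0.0837 and 0.191 (cameraPR). With the log2 fold change as the statistic the gypsy-group and heat shock lists passed, and the other 6 lists had adjusted p from 0.0514 to 0.191 (cameraPR).

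Factors of piRNA biogenesis were lower after Armitage knockdown in 8 of 16 cases and higher in 0 (0 also at an unadjusted p under 0.05), and these were also the counts adjusted over the list alone (list adjusted p = 0.00131, cameraPR). Besides the targeted gene, zuc, which encodes the endonuclease Zucchini, stood at −0.65 ± 0.25, piwi at −0.52 ± 0.08, mino at −0.34 ± 0.11, vret at −0.30 ± 0.10, shu at −0.29 ± 0.09 and Hel25E at −0.25 ± 0.07 in the authors' deposited table, all past the test. Left without fs(1)Yb and armi, an alternative chosen after seeing the data, the list no longer passed (adjusted p = 0.202, cameraPR), with 6 of 14 members lower. Nuclear silencing factors acting with Piwi mostly did not pass. Of 17, wde rose by 0.86 ± 0.19, piwi fell, and 15 did not pass, among them egg at −0.10 ± 0.08 and Panx at 0.09 ± 0.15 in the authors' deposited table, with 1 and 1 adjusted over the list alone (list adjusted p = 0.638, cameraPR).

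**Figure D2:**
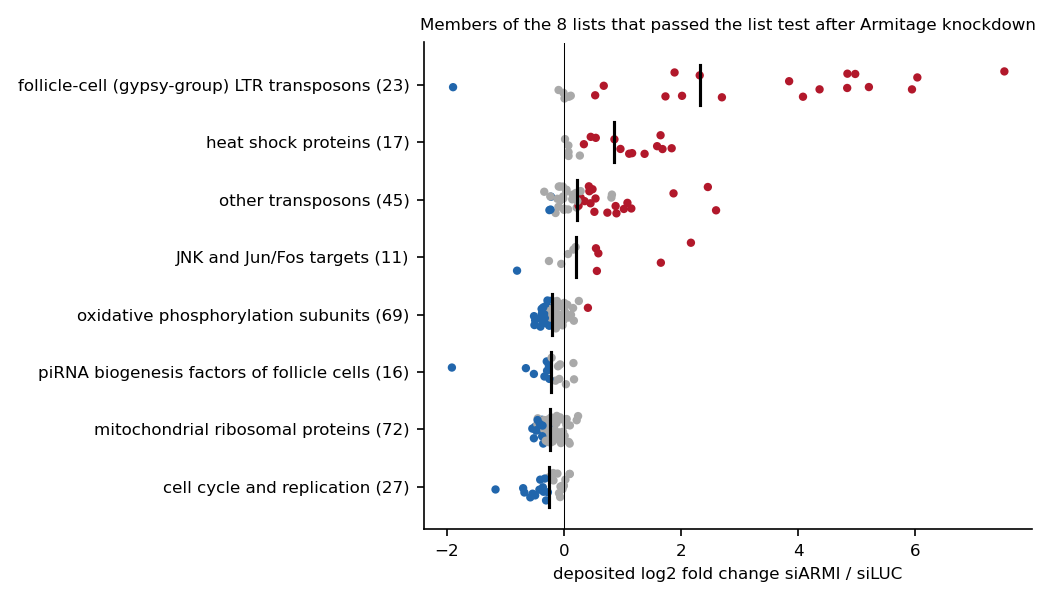
Members of the 8 lists that passed the list test after Armitage knockdown, with the deposited log2 fold change (siARMI over siLUC) on the x axis and the number of measured members in brackets. Red points are called higher, blue points called lower, grey points did not pass, and black bars are list medians, from −0.27 for cell cycle and replication to 2.32 for gypsy-group transposons.

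Yb knockdown gave 16 called rows in the authors' deposited table, 12 higher and 4 lower, of which 10 were transposon rows. The sense rows of 8 gypsy-group transposons rose, with mdg1 at 5.18 ± 0.50, 297 at 4.17 ± 0.47, Tabor at 3.75 ± 0.55, Stalker2 at 3.65 ± 0.46, blood at 3.11 ± 0.78, 412 at 3.05 ± 0.51, Quasimodo at 2.76 ± 0.51 and Stalker at 2.58 ± 0.55 in the authors' deposited table. Antisense rover was lower at −2.47 ± 0.52 and antisense gypsy5 was called lower with an estimate shrunk to 0 (adjusted p = 0.0488, Benjamini-Hochberg, in the authors' deposited table). The gypsy-group list had 8 members higher, 0 lower and 15 not past the test, with 8 and 0 adjusted over the list alone, and no sense row with a negative sign had an unadjusted p under 0.05 (list adjusted p = 5.71e-85, cameraPR). The other transposons did not pass as a list (adjusted p = 0.0568, cameraPR). Their adjusted p (cameraPR) was 0.00113 with the filter on expression, 0.175 by ranks, 0.499 with a preset correlation of 0.05 and 0.933 with the log2 fold change. Sense transposon rows were called higher in 8.89% of 90 cases and genes in 0.0482% of 8295 (p = 6.13e-14, Fisher's exact test, two-sided).

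Among genes, Yb knockdown raised TM4SF, a tetraspanin gene, by 3.81 ± 0.60, the receptor tyrosine kinase gene Ret by 2.94 ± 0.54 and ex by 2.23 ± 0.56 in the authors' deposited table. NetA was called lower (adjusted p = 0.00319, Benjamini-Hochberg, in the authors' deposited table), with an estimate shrunk to 0. The histone gene row His2B:CG33902 was called higher (adjusted p = 0.0384, Benjamini-Hochberg, in the authors' deposited table), also with an estimate shrunk to 0. It shares its sequence with many histone copies, so its count is uncertain. With fs(1)Yb these were the 6 called genes of 8295 tested. Outside the transposon lists, 4 of the 592 list members had an unadjusted p under 0.05 in the authors' deposited table. The siYB p-values leaned toward 1: 66 rows had an unadjusted p under 0.05 in the authors' deposited table, where chance alone would give 423.9, so the absence of a call in this table carries little information.

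The markers of cell types other than follicle cells did not pass as lists in either comparison. After Armitage knockdown the adjusted p (cameraPR) was 0.650 for germ cells, 0.540 for muscle, 0.781 for neurons and glia and 0.650 for hemocytes and fat body, and after Yb knockdown it was 0.895, 0.531, 0.895 and 0.526. Single members changed in the authors' deposited table after Armitage knockdown, such as the muscle marker Zasp66, which fell by 4.00 ± 0.21, the neuron marker Rim at 3.89 ± 0.69, AGO3 of the germline piRNA pathway at 1.82 ± 0.25, Nxf3 at −1.46 ± 0.21, the collagen IV gene Col4a1 at −1.29 ± 0.15 and the hemocyte factor srp at 1.05 ± 0.19. Rim was near the floor, with a mean normalised count of 0.60 in the siYB table against a lower quartile of 14.03. Over their lists alone, the members higher and lower after Armitage knockdown were 5 and 3 for germ cells, and 2 and 2 for muscle, for neurons and glia, and for hemocytes and fat body, the same as over all genes.

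The 16 rows called after Yb knockdown were all called after Armitage knockdown in the same direction, as read from the authors' deposited tables. In 3 of them, NetA, antisense gypsy5 and His2B:CG33902, the siYB estimate was shrunk to 0, so its direction is uncertain. The 12 higher rows compare with 1.81 given by independent lists of these sizes, and the 4 lower rows with 0.544, and simulated unchanged groups gave 0 shared calls, which sets no bound since unchanged groups are hardly called at all. Part of the excess may come from the shared controls, which could not be split without per-library values. TM4SF was higher by 3.23 ± 0.16 after Armitage knockdown, Ret by 3.57 ± 0.10 and ex by 2.45 ± 0.12 in the authors' deposited table. Of 538 rows called after Armitage knockdown with an absolute log2 fold change of at least 1, 88.5% had the same sign after Yb knockdown, and of all 2398 called rows 73.1% did. For rows shrunk to 0 the siYB sign is uncertain. The share was 60.7% of the rows not called and 66.7% (equal spread) or 54.4% (wider siYB spread) of simulated unchanged rows. With siARMI effects as deposited, no siYB effect and rows chosen in the same way, simulation with shared controls gave 57.7% (equal spread) or 52.0% (wider siYB spread) for the rows of at least 1, and 60.0% or 52.3% for all called rows. Across rows, which are not independent replicates, the log2 fold changes had a Pearson r of 0.299 and a Spearman rho of 0.287, and the signed quantiles of p 0.485 and 0.343. Shared controls alone, simulated as signed quantiles, gave 0.499 and 0.482 with equal spread and 0.140 and 0.133 with the wider siYB spread, so the quantile correlations exceeded chance only under the latter. The covariance of the signed quantiles was 1.18, against 0.496 (equal spread) or 0.141 (wider siYB spread) from shared controls alone, and it was 0.150 in features called in neither table. The simulated quantiles had the spread that chance gives, a median absolute value of 0.674. That median was 0.353 in the siYB table and 1.41 in the siARMI table. The covariances are therefore on unlike scales and set no bound.

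**Figure D3:**
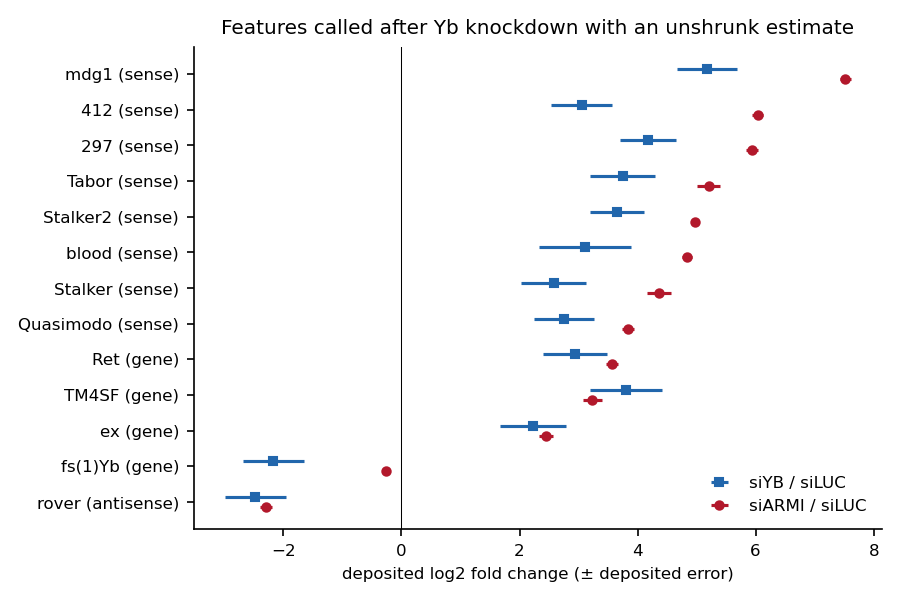
The 13 features called after Yb knockdown whose estimate was not shrunk to 0, with the deposited log2 fold change on the x axis after Yb knockdown (blue squares) and Armitage knockdown (red circles) and bars for the error in the authors' deposited tables. The direction was the same in both knockdowns, for example mdg1 at 5.18 and 7.52 and ex at 2.23 and 2.45.

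The size of the change was compared between the knockdowns for the 22 features whose siYB estimate had not been shrunk to 0. Of these 7 differed, or 14 with the shared-control covariance removed, and the largest difference among those 7 was that of 412, at 2.98 ± 0.52 (siARMI minus siYB, from the authors' deposited tables; adjusted p = 2.40e-07, two-sided normal test, Benjamini-Hochberg). For ex the difference was 0.22 ± 0.57 (adjusted p = 0.724, two-sided normal test, Benjamini-Hochberg) and for Ret 0.63 ± 0.55, both from the authors' deposited tables.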

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

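The tests of the siYB table described here, and the limit of the difference test to 22 features, were chosen after the result was seen. Between the knockdowns 7 features differed in the test of the difference itself (siARMI minus siYB log2 fold change from the authors' deposited tables). Sense rows of 6 gypsy-group transposons were higher after Armitage knockdown than after Yb knockdown, 412 by 2.98 ± 0.52, mdg1 by 2.34 ± 0.51, Stalker by 1.78 ± 0.58, 297 by 1.77 ± 0.49, Tabor by 1.46 ± 0.59 and Stalker2 by 1.32 ± 0.46. The seventh is fs(1)Yb, itself targeted in siYB, with a difference of 1.91 ± 0.52. The errors ignore the covariance of shared controls, and with it removed 14 features passed. The 2 tables were shrunk separately, and knockdown efficiency was not matched (−2.17 for fs(1)Yb and −1.92 for armi, each in its own table), so the differences do not rank the 2 factors.

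The p-values of the siYB table pile up toward 1 (median 0.724) and nearly all of its fold changes were shrunk to 0. Shallow sequencing alone is argued against by the abundant features, where counting noise is least. The median absolute quantile of p was 0.211 (0.201 to 0.222) in the top 25% of features by expression and 0.817 in the lowest 25%, and chance gives 0.674. Lower depth may still contribute. If both tables used the same controls and size factors from ratios to a geometric mean, the geometric mean depth would be 13.6 times lower in siYB than in siARMI. Very unequal depth among the siYB libraries could also give that value. An absence of any transposon effect beyond the called rows stays open: 16 sense rows higher by log2 1 or more after Armitage knockdown and not called after Yb knockdown had a median siYB log2 fold change, rebuilt from the mean counts, of 0.78, but the siARMI fold that chose them enters that value, and of the 8 outside the lowest 25% by expression 7 lay above the spread of uncalled rows and 2 had an unadjusted p under 0.05 in the authors' deposited table. Wide differences among the siYB libraries could give the pile-up of p-values toward 1, and the errors of the 13 called and unshrunk features were a median of 5.00 times those of the siARMI table. Which libraries differ, and whether one was mislabelled or transfected poorly, cannot be told apart without per-library values, and a biological difference between the knockdowns stays open.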

How the results depend on the processing

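The transposon strand split, the list tests without fs(1)Yb and armi or without Hsp70 copies, the signed quantile and the limit to unshrunk features were chosen after seeing the data; the other alternatives were fixed before the data were examined. Of 640 alternative values 35 counts or correlations moved, 11 values of single lists lost their call and 5 gained one, and 30 values turned direction, each of a list that did not pass under either setting (cameraPR). Rows below count genes and transposons together unless named, and calls come from the authors' deposited tables.

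With an absolute log2 fold change of at least 1, Armitage knockdown gave 559 called features (352 higher, 207 lower), of which transposons made 44 (29 higher, 15 lower). Holm adjustment gave 927 (546 higher, 381 lower), with 50 transposons (31 and 19). Both follow from the stricter criterion. By strand, 46 sense rows (5 lower) and 32 antisense rows (8 higher) were called. After Yb knockdown the minimum fold left 2 lower features and 1 lower transposon, since estimates shrunk to 0 drop out. At an adjusted p under 0.01 and with Holm adjustment 1 transposon was lower. Sense rows gave 0 lower (0 also at unadjusted p under 0.05) and antisense rows 2 calls, 0 higher (1 at unadjusted p under 0.05).

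Lists that passed after Armitage knockdown (cameraPR) numbered 5 with a preset correlation of 0.05 and 2 with the log2 fold change as statistic, against 8. After Yb knockdown they numbered 3 with the log2 fold change, 3 with the expression filter and 0 with genes only (2 at unadjusted p under 0.05), against 1; genes only leaves out the transposon list that passed. The lists that gained a call were, after Yb knockdown, other transposons (0.00113, expression filter), piRNA biogenesis (0.00546, expression filter; 0.00154, log2 fold change) and Hippo (0.00149, log2 fold change), and after Armitage knockdown proteasome subunits (0.00641, ranks), as adjusted p. With the log2 fold change the piRNA biogenesis and Hippo calls rest on fs(1)Yb, the siRNA target, and on ex, since the other members were shrunk to 0. Without fs(1)Yb and armi the piRNA biogenesis list had an adjusted p of 0.888 (cameraPR). For the others the cause was not tested.

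After Armitage knockdown the lists that turned, with their adjusted p (cameraPR), were Hedgehog (0.424) and oxidative stress (0.663) by ranks, Hedgehog (0.928), Hippo (0.945), cytosolic ribosomal proteins and unfolded protein response (both 0.933) with the log2 fold change, and neurons and glia (0.916) with the expression filter. After Yb knockdown 23 values turned, by ranks at an adjusted p of 0.964, with the log2 fold change at 0.933, with genes only at 0.997 for ecdysone response, and with the expression filter at 0.685 for follicle cell identity, 0.968 for antiviral and Hedgehog lists and 0.989 for germ cell and neuron lists (cameraPR). The cause was not tested.

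The overlap of lower calls was 1 with the minimum fold, against 4. Pearson's r between the knockdowns was 0.535 (Spearman 0.208) in features above the median expression, 0.171 (Spearman 0.276) without fs(1)Yb, armi and transposons, against 0.299 (Spearman 0.287) in all, and 0.0166 (Spearman 0.178) in features called in neither table, where the called features were removed by construction. The difference test called 14 features with the shared-control covariance removed and 11 at an adjusted p under 0.1 (normal test, Benjamini-Hochberg), against 7.

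No paired analysis was possible because the tables hold no per-library values. For the same reason DESeq2, other filters on low counts, the replicate block, leaving out replicates, fry, an estimated correlation, and other splits of the samples were not run. Depth per library is unknown. If both tables used the same siLUC libraries and size factors from ratios to a geometric mean, the scale of 3.69 between their mean counts bears on depth. It would put the geometric mean depth of the siYB libraries 13.6 times below that of the siARMI libraries, evenly spread or not.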

Other observations

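Several gene groups that did not pass as lists held strong changes after Armitage knockdown. The authors' deposited table lists the cell death gene hid at 4.19 ± 0.33 and the caspase gene Drice at 0.53 ± 0.08, while the ribonucleotide reductase genes RnrS and RnrL stood at −0.68 ± 0.08 and −0.53 ± 0.07. The apoptosis and DNA damage list had 6 members higher and 11 lower of 25 (adjusted p = 0.235, cameraPR). The list of Notch pathway genes and E(spl) targets had 4 higher and 0 lower of 13 (adjusted p = 0.235, cameraPR), among them E(spl)m7-HLH at 1.77 ± 0.16 in the authors' deposited table. In the JAK-STAT and antiviral list 7 of 13 were higher and 2 lower (adjusted p = 0.235, cameraPR), with Stat92E at 0.70 ± 0.07, the cytokine upd3 at 1.05 ± 0.18 and Vago at −1.13 ± 0.12 in the authors' deposited table. In the Hedgehog list 3 of 11 were higher and 2 lower (adjusted p = 0.738, cameraPR). The Hedgehog receptor ptc was lower at −1.25 ± 0.07 and its ligand hh at −0.70 ± 0.11 in the authors' deposited table. Of the Hippo list, 6 of 14 were higher and 5 lower (adjusted p = 0.629, cameraPR), with crb at −1.30 ± 0.16 and Diap1 at −0.50 ± 0.09 in the authors' deposited table.

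Follicle cell identity genes went both ways, 10 higher and 8 lower of 23 (adjusted p = 0.199, cameraPR). The polar and stalk cell marker genes cas and Fas3 were higher by 2.53 ± 0.20 and 2.13 ± 0.18 and bab2 lower at −1.17 ± 0.10 in the authors' deposited table, and the eggshell gene dec was higher by 1.15 ± 0.07 there. Of 35 proteasome genes 15 were higher and 1 lower (adjusted p = 0.235, and 0.00641 by ranks, cameraPR). Prosbeta2R2, the member that was lower, stood at −2.08 ± 0.37 in the authors' deposited table. Cytosolic ribosomal protein genes had 7 higher and 4 lower of 87 (adjusted p = 0.704, cameraPR). The immune effector, small RNA machinery, unfolded protein, oxidative stress, Hedgehog, ecdysone, eggshell, lipid metabolism and insulator lists had adjusted p from 0.202 to 0.738 (cameraPR). After Yb knockdown the lists of genes, transposons aside, had adjusted p from 0.120 for piRNA biogenesis to 0.992 (cameraPR).

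Of the tests below, those of strand assignment and of library scaling were chosen only after the result was seen. After Armitage knockdown 24 of 93 antisense transposon rows fell and 61 did not pass, while 41 of 91 sense rows rose. Sense reads placed on the wrong strand would raise both rows of a family, but of 22 families called higher in sense and called in antisense 18 (81.8%) were lower in antisense. Misplaced sense reads alone thus do not give the fall in those families. The count uses the rows that make up the pattern, so it is no separate evidence on strand assignment. Library scaling by abundant transposons would lower genes too. Genes in the top 25% by expression had a median log2 fold change of 0.024, and all rows together had −0.0055. Normalisation to the typical row would put genes near 0 in any case, so the gene median cannot decide on scaling. The called antisense rows, chosen for having changed, had −0.83 and all antisense rows −0.09. The antisense loss was larger in the gypsy-group list. Its 23 antisense rows had a median 0.85 below that of 61 families outside it (difference −0.85, two-sided permutation p = 1e-05, the smallest these permutations can give). Antisense G6 and 3S18, outside the list, fell too, at −1.45 ± 0.11 and −1.33 ± 0.15, while antisense blood, in the list, stood at 0.08 ± 0.10. Families were not matched on expression. Some outside the list had low mean antisense counts, such as Circe at 3.4, against 5188 for gypsy. Shrinkage toward 0 at low counts may therefore add to the difference, and its share was not measured. Some families outside the list were well counted in antisense and fell little. Antisense TART-A (mean count 6486) stood at −0.42 ± 0.06 and antisense flea (1488) at −0.34 ± 0.07. In the list, antisense gtwin (4856) stood at −1.57 ± 0.07 and antisense springer (3156) at −0.02 ± 0.06. Whether the loss scales with the sense rise stays open, with a Spearman rho of −0.26 across 84 families (bootstrap 95% interval −0.47 to −0.04, permutation p = 0.0175), and families are not independent replicates.

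The fall of the cell cycle, oxidative phosphorylation and mitochondrial ribosomal lists after Armitage knockdown was set against gene length and expression level. Among 10000 random lists matched on gene length, 0 had a median as low as any of the 3 lists, and matched on expression level 0 did as well (percentile 0 in both). The list medians were −0.27, −0.21 and −0.23, and those of the matched random lists lay between −0.018 and 0.015. Neither trend therefore gives the fall, which may be biological or come from differences in growth or density between cultures that no table here measures.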
